A study of Drosophila melanogaster with 25 samples.

How the data were processed

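RNA-seq of 25 libraries was used, each a separate biological replicate of 16–20 h embryos, L3 wing discs or L3 eye-brain complexes, kept at 25 C. Per the labels' protocols, RNA was extracted with the ReliaPrep tissue kit, and 10 ng of total RNA with a RIN above 8 was made into cDNA with the SMARTer Ultra Low kit, sonicated, ligated to adapters and amplified for 12 to 15 cycles. Paired reads of 150 bases were sequenced, on a NovaSeq X Plus for the embryos and the ft null set and on a NovaSeq 6000 for the wing discs and the eye-brain FtICD set, per the labels. The kit as named does not keep the strand, so the counts of genes whose exons overlap cannot be fully told apart; such overlaps of at least 50 bases are named beside the gene.

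The deposited values were treated like expected counts per gene, not scaled for library size, in 2 tables with 17208 genes and 25 columns, all used. The submitters' processing notes name FastQC 0.10, Trimmomatic 0.33, Salmon 1.80 and edgeR with the build dm6, without giving their settings. Of the nonzero values 31.8% were not whole numbers (tolerance 1e-06), and all values were rounded to whole counts. How Salmon was used is not stated. Of the values of at least 100, 56.8% were whole in the FtICD table and 70.4% in the ft null table, which scaling by gene length would not leave. Gene symbols were matched to Ensembl release 115 of BDGP6.54, which places 17083 of the genes and gives the coordinates printed here. None of the 28 pairs of libraries within groups held duplicated values, the chi-square per degree of freedom of each pair being 7.96 or higher.

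Comparisons were made in R 4.3.3 with edgeR 4.0.16. Each of the 4 comparisons used its own libraries: FtICD against wild type in embryos (4 and 4), wing discs (3 and 3) and eye-brain complexes (3 and 2), and ft null against its own wild type (3 and 3). Genes were filtered by group with filterByExpr (minimum count 10), libraries were scaled by TMM, and edgeR's two-sided quasi-likelihood F test was applied with Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. No replicate block was used. The biological coefficient of variation was 14.9% in embryos, 20.6% in wing discs, 33.7% in eye-brain FtICD and 11.9% in the ft null set. Standard errors of log2 fold changes are from the same fits. CPM values use TMM-scaled library sizes. Differences of FtICD effects between tissues, and of ft null and FtICD effects in eye-brain complexes, were tested as interaction terms with 1 mean per group. For genes with 0 counts in a group, a bound against a floor of 3 counts over the group is given, and for genes with 1 to 3 counts a ratio with a 95% exact interval.

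The 27 gene lists, the comparisons, the tests, the alternatives and the rule for named genes were set before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The lists were also tested with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. None of the 25 list calls held with an estimated correlation. Counts "adjusted over the list alone" use Benjamini-Hochberg within the list.

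Named genes were chosen by a rule. Always named were ft, w, roX1 and roX2. For each comparison the rule took the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM whose groups did not overlap, leaving out symbols that are only annotation numbers. From each list it took up to 4 members with the smallest adjusted p, or up to 2 of the highest level where none passed. It also took up to 10 genes per direction called in all 3 FtICD tissues or in both eye-brain comparisons, and up to 6 genes of each interaction test. The text names a subset of these, and says where a gene was chosen after its values were seen.

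The low-recovery genes were defined after the data were examined. They have a mean above 5 CPM in the 6 libraries of the ft null table. Their mean log2 CPM there is at least 2 (4-fold) above that of 4 eye-brain libraries of the FtICD table. Those libraries are FtICD replicates 1 and 2 and both wild-type replicates. The GC content of the low-recovery genes was not analysed here.

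The procedure was tested on simulated data with counts drawn from the means and library sizes of each comparison and 200 genes changed. Of 1.5-, 2- and 4-fold changes the embryo design recovered 52.2%, 77.6% and 97%, the wing disc design 13.4%, 76.1% and 90.9%, the eye-brain FtICD design 0%, 10.4% and 60.6%, and the ft null design 68.7%, 83.3% and 95.5%. Unchanged genes called numbered 8, 9, 7 and 15. The wing disc against embryo interaction test recovered 90% of 4-fold differences. A list with every member shifted 2-fold was found in each of the 4 comparisons, with 2, 1, 1 and 2 other lists called. Genes were drawn independently, so this check does not cover correlation among the genes of a list or smaller shifts.

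Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a stricter filter of 1 CPM, limma-voom, a replicate block, a joint fit of the FtICD tissues, a minimum 2-fold change, and leaving out each library in turn. Chosen after the data were seen were leaving out ribosomal RNA genes, a correction for gene length per library, leaving out the low-recovery genes, and leaving out eye-brain FtICD replicate 3 from the interaction tests and overlaps. Other splits of the libraries into groups of the same sizes were fitted for the comparisons with at least 3 libraries per group. Counts of a group's outlying libraries used Dixon's criterion in groups of 4.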

Results

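RNA of Drosophila melanogaster was sequenced from 25 libraries of 3 tissues. The series asks how RNA levels change when the activity of fat (ft), the gene of a giant cadherin that acts in growth control and planar polarity, is altered. FtICD libraries came from animals in which ubi-Gal4 drove UAS-FtICD-3xFLAG, a tagged intracellular domain of Fat. They were made from 16–20 h embryos (4 FtICD, 4 wild type), L3 wing discs (3 and 3) and L3 eye-brain complexes (3 FtICD, 2 wild type). A separate table held eye-brain complexes of the ft null ft fd5-5/ftX13 (3 libraries) with their own wild type (3 libraries). Wild type was w1118 throughout. Total counts per library ranged from 23642594 to 28000708 in FtICD embryos and from 24827492 to 30046844 in wild-type embryos. They ranged from 39391778 to 46919376 in FtICD wing discs and from 30886102 to 54256669 in wild-type discs. The eye-brain FtICD libraries held 31382563 to 41037756 counts and their wild type 30361047 and 32970570. The ft null libraries held 16458028 to 21001535 counts and their wild type 15016561 to 16266881.

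The targeted gene itself, ft (FBgn0001075, 2L, 4198404 to 4221796), was higher in every FtICD library than in every wild-type library of the same tissue. Levels are given as counts per 1000000 library counts (CPM). In embryos ft was at 1191 ± 154 CPM (SD, n = 4) against 25.4 ± 5.04 (SD, n = 4), a log2 fold change of 5.55 ± 0.16 (SE, adjusted p = 1.1e-08). In wing discs it was at 8361 ± 810 CPM (SD, n = 3) against 313 ± 27.8 (SD, n = 3), a log2 fold change of 4.74 ± 0.12 (SE, adjusted p = 1.3e-05). In eye-brain complexes it was at 4762 ± 397 CPM (SD, n = 3) against 147 ± 7.72 (SD, n = 2), a log2 fold change of 5.02 ± 0.15 (SE, adjusted p = 8.2e-04). In the ft null, ft RNA was also higher than in its wild type. It was at 170 ± 11.6 CPM (SD, n = 3) against 117 ± 6.79 (SD, n = 3), a log2 fold change of 0.54 ± 0.07 (SE, adjusted p = 9.5e-04). Counts per gene do not separate the transgene's RNA from that of the resident gene.

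**Figure D1:**
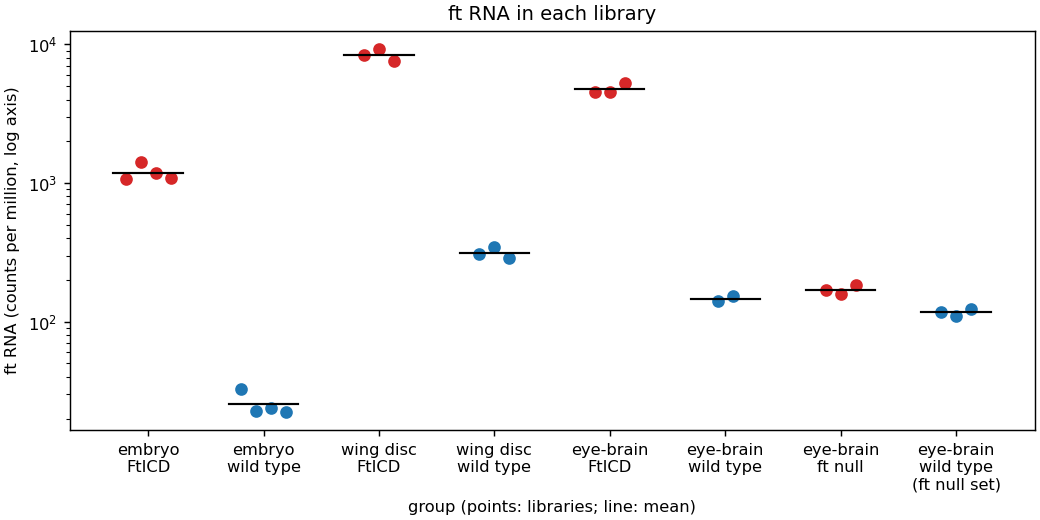
Level of ft RNA in CPM (log axis) in each of the 25 libraries, by group; points are libraries, lines are group means, FtICD or ft null in red and wild type in blue. FtICD groups have means of 1191, 8361 and 4762 in embryo, wing disc and eye-brain, against 25.4, 313 and 147 in their wild type, and the ft null has a mean of 170 against 117.

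The white gene w, whose functional copy usually marks transgenes in w1118 animals, was higher in FtICD embryos by a log2 fold change of 3.50 ± 0.35 (SE, adjusted p = 2.0e-05). In wing discs w was at 204 ± 36.7 CPM (SD, n = 3) with FtICD and held 2 counts over the 3 wild-type libraries, a ratio of 12300 with a 95% interval of 3400 to 101000. This interval, and the others on counts given here, covers counting error alone. In eye-brain complexes w was higher with FtICD by 5.18 ± 0.60 (SE, adjusted p = 0.023). The call was lost without FtICD replicate 1 (adjusted p = 0.11) or wild-type replicate 2 (adjusted p = 0.055). In the ft null set w stayed at or below 1.19 CPM in each of the 6 libraries. The male-specific RNAs lncRNA:roX1, whose exons overlap those of ec, and lncRNA:roX2, which act in X-chromosome dosage compensation, differed in FtICD embryos by log2 fold changes of 0.87 ± 0.09 and 0.93 ± 0.11 (SE, adjusted p = 2.0e-05 and 4.8e-05). In a joint fit of the FtICD tissues neither passed (adjusted p = 0.17 and 0.42). In wing discs lncRNA:roX1 varied within groups, at 138 CPM in FtICD replicate 2 and 96.1 in wild-type replicate 3 against 252 to 416 in the remaining libraries. In eye-brain FtICD replicate 1, lncRNA:roX2 was at 0.175 CPM against 29.1 to 70.2 in the other 4 libraries. These RNAs were included as a readout of the mix of sexes, which may therefore differ between libraries. Its part in the counts of genes called was not tested. In the ft null lncRNA:roX1 was lower by a log2 fold change of -0.95 ± 0.17 (SE, adjusted p = 3.0e-03).

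The libraries also differed in composition. Ribosomal RNA took 13.9 ± 1.83% of counts in FtICD embryos (SD, n = 4) and 4.78 ± 0.838% in wild-type embryos (SD, n = 4). It took 13.0 ± 1.94% against 11.0 ± 0.160% in wing discs (SD, n = 3 each). In eye-brain FtICD it took 8.09 ± 3.19% (SD, n = 3) against 13.2 ± 2.61% (SD, n = 2), and in the ft null set 0.642 ± 0.148% against 1.19 ± 0.249% (SD, n = 3 each). Ribosomal 28S RNA held 0 counts in 5 libraries of the ft null table and 45 in the sixth, against 676597 or more in each library of the FtICD table. The ribosomal shares of the 2 tables may therefore not measure the same thing, and the cause of this gap was not tested. A set of 455 genes was at least 4-fold lower in the mean of 4 eye-brain libraries of the FtICD table than in the ft null table. The 4 libraries were FtICD replicates 1 and 2 and both wild-type replicates. Their mean log2 CPM was set against that of the 6 libraries of the ft null table. These low-recovery genes, defined from the data, include Hsc70-4, the gene of an abundant cytosolic chaperone. Hsc70-4 was at 46.1 to 87.6 CPM in those 4 libraries, at 3627 CPM in eye-brain FtICD replicate 3 and at 7464 to 12801 CPM in the ft null table. Of the set, 30.9% lay on the X chromosome, against 16.3% of 7547 other genes. Its median level in wing discs was lower in all 3 FtICD libraries (log2 -3.73 to -3.53) than in the wild type (-3.36 to -2.35).

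**Figure D2:**
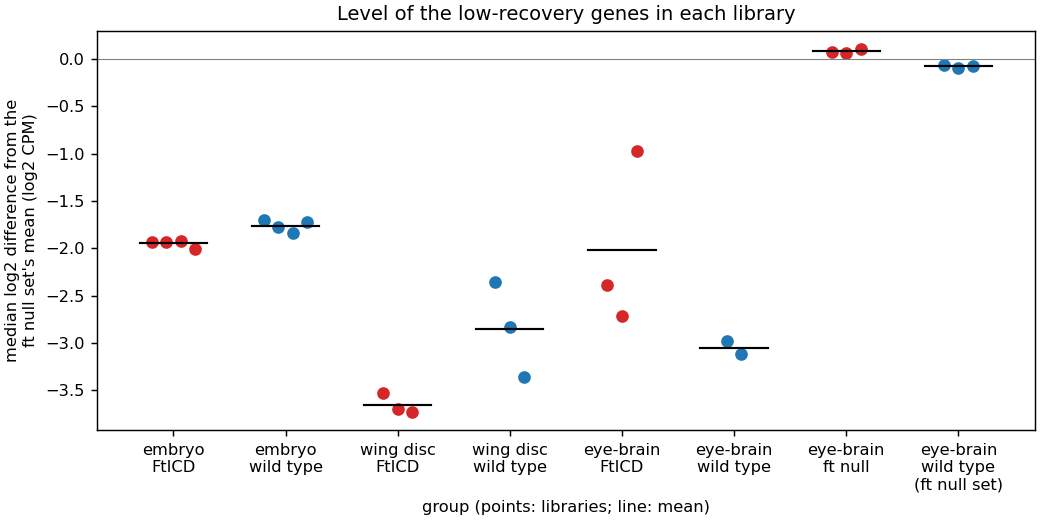
Median log2 difference of the 455 low-recovery genes from their mean in the ft null table (log2 CPM), for each library; points are libraries, lines are group means, FtICD or ft null in red and wild type in blue. Eye-brain FtICD replicate 3 lies at -0.97, the other 4 eye-brain libraries of its table between -3.12 and -2.39, and the embryos between -2.01 and -1.70.

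In FtICD embryos (n = 4 against 4), 13 of 16 neuronal genes tested were higher, while 55 of 86 ribosomal protein genes and 21 of 33 genes of respiratory complex I were lower (camera, adjusted p = 2.7e-03, 1.7e-05 and 1.2e-03). With an estimated correlation the adjusted p of each was 0.80. Single genes changed more. Syngr (FBgn0033876, 2R, 13841761 to 13846255), the gene of the synaptic vesicle protein synaptogyrin, rose from 3.87 ± 0.583 to 49.3 ± 3.12 CPM (SD, n = 4 each), a log2 fold change of 3.67 ± 0.12 (SE, adjusted p = 1.1e-08). Map205, which codes for a microtubule-associated protein, rose by 3.66 ± 0.14 on the log2 scale (SE, adjusted p = 3.0e-08). The translation initiation factor gene eIF4E3 fell from 25.3 ± 2.50 to 0.883 ± 0.200 CPM (SD, n = 4 each), a log2 fold change of -4.83 ± 0.15 (SE, adjusted p = 1.1e-08). The cuticle protein gene Cpr67Fa1 was at -2.59 ± 0.09, Pepck2, of gluconeogenesis, at -2.47 ± 0.11, and Lasp, of an actin-binding protein, at -2.35 ± 0.07 (log2 fold change ± SE, adjusted p = 1.5e-08, 9.0e-08 and 1.1e-08).

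Of the 15 heat-shock genes tested in embryos, 12 were higher and 1 lower, over all genes and adjusted over the list alone. Hsp70Bb, which codes for an inducible chaperone, differed by a log2 fold change of 4.58 ± 0.77, Hsp26 by 3.80 ± 0.74 and Hsp22, whose exons overlap CG4456, by 4.24 ± 0.84 (SE, adjusted p = 5.7e-04, 1.5e-03 and 1.6e-03). Their level varied most among the FtICD libraries, Hsp70Bb being at 796 CPM in replicate 1 and at 93.9 to 175 CPM in the other 3. Tested against all other genes with camera, the heat-shock list did not pass (adjusted p = 0.11), whereas with a replicate block it did (2.0e-03). With an estimated correlation it did not (0.83).

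Of 16 neuronal genes tested, 13 were higher and none lower, both over all genes and adjusted over the list alone (camera, adjusted p = 2.7e-03; adjusted p = 0.80 with an estimated correlation). Snap25, a synaptic fusion protein gene, rose by 1.11 ± 0.12 on the log2 scale and VGlut, the vesicular glutamate transporter gene, by 0.81 ± 0.07 (SE, adjusted p = 2.9e-05 and 8.0e-06). The mitochondrially encoded genes were higher in 12 of 13 cases, and in 13 adjusted over the list alone. Among them mt:ND5 was at a log2 fold change of 1.10 ± 0.10 (SE, adjusted p = 1.4e-05). This list passed camera (adjusted p = 1.7e-05; adjusted p = 0.80 with an estimated correlation). Mitochondrial genes took 1.82 ± 0.251% of counts with FtICD and 0.719 ± 0.141% in wild type (SD, n = 4 each).

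Nuclear genes of the respiratory chain moved the other way in FtICD embryos. Of 33 complex I genes, 21 were lower and 1 higher (22 and 1 adjusted over the list alone), and the list passed camera (adjusted p = 1.2e-03; adjusted p = 0.80 with an estimated correlation). ND-PDSW fell by 0.89 ± 0.06 on the log2 scale, whereas ND-MLRQ rose by 1.03 ± 0.09 (SE, adjusted p = 2.4e-06 and 1.3e-05). Of 33 genes of complexes II to V, 24 were lower and 3 higher, with the same counts adjusted over the list alone (camera, adjusted p = 7.3e-04; adjusted p = 0.80 with an estimated correlation). Among them the cytochrome oxidase gene COX5A was at -0.71 ± 0.06 (log2 fold change ± SE, adjusted p = 1.1e-05). In glycolysis, 8 of 13 genes were lower and none higher (9 lower adjusted over the list alone; camera, adjusted p = 2.7e-03; adjusted p = 0.80 with an estimated correlation). Ldh, of lactate dehydrogenase, was at -1.03 ± 0.07 (log2 fold change ± SE, adjusted p = 2.4e-06). Ribosomal protein genes were lower in 55 and higher in 12 of 86 cases (57 and 12 adjusted over the list alone; camera, adjusted p = 1.7e-05; adjusted p = 0.80 with an estimated correlation). Among these, sta was at -1.16 ± 0.09 and RpS26 at -0.87 ± 0.07 (log2 fold change ± SE, adjusted p = 6.3e-06 and 5.9e-06).

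Cell cycle genes were lower in 13 and higher in 2 of 28 cases in embryos (14 and 2 adjusted over the list alone). The gene of the replication licensing inhibitor geminin was at -1.08 ± 0.08 and PCNA at -0.84 ± 0.12 (log2 fold change ± SE, adjusted p = 4.6e-06 and 2.4e-04). The list passed camera (adjusted p = 0.037; adjusted p = 0.80 with an estimated correlation), a call lost without FtICD replicate 3 (adjusted p = 0.054), wild-type replicate 1 (0.069) or wild-type replicate 3 (0.056). Of 19 targets of Yorkie, the coactivator that Hippo signalling restrains, 4 were higher and 3 lower (3 and 3 adjusted over the list alone). They included chinmo at 0.79 ± 0.07, the glypican gene dally at 0.56 ± 0.07 and Mer at -0.63 ± 0.09 (log2 fold change ± SE, adjusted p = 1.3e-05, 1.1e-04 and 1.8e-04). The Yorkie target list had a median log2 fold change of 0.05 and a mean of -0.14 and did not pass camera (adjusted p = 0.93). Of 23 Hippo pathway genes, 5 were higher and 10 lower, also when adjusted over the list alone (camera, adjusted p = 0.39), with jub at -0.74 ± 0.10 (log2 fold change ± SE, adjusted p = 1.3e-04). Cuticle genes were lower in 43 and higher in 18 of 113 cases, also when adjusted over the list alone (camera, adjusted p = 0.12).

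By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6000 of 11422 genes tested passed in embryos, 3053 higher and 2947 lower, of which 711 and 560 changed at least 2-fold. In each gene named as changed in any comparison, all libraries of the FtICD or ft null group lay on the same side of all wild-type libraries. Chance gives this to 2.86% of genes with 4 against 4 libraries, 10% with 3 against 3 and 20% with 3 against 2. Many of these genes were chosen for such separation or for a small adjusted p, so it is no separate support for them. Some called genes with overlapping groups were left unnamed. The share of ribosomal RNA and of mitochondrial counts went with genotype in embryos, and so does any difference of the stocks other than the transgene, since the control is w1118.

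In FtICD wing discs (n = 3 against 3), 11 of 26 genes of synthesis of and response to ecdysone, the moulting hormone, were lower, and 17 of 58 genes of detoxifying enzymes were higher (camera, adjusted p = 1.0e-05 and 2.7e-05). With an estimated correlation the adjusted p was 0.36 and 0.15. Blimp-1 (FBgn0035625, 3L, 5630983 to 5652094), an ecdysone-induced repressor gene that times pupation, fell from 53.9 ± 20.0 to 0.986 ± 0.890 CPM (SD, n = 3 each), a log2 fold change of -5.77 ± 0.63 (SE, adjusted p = 1.8e-03). The nuclear receptor gene Hr4 was at -4.39 ± 0.61, ImpE3 at -2.76 ± 0.24, ImpE1 at -2.26 ± 0.20 and Eip78C at -2.24 ± 0.20 (log2 fold change ± SE, adjusted p = 4.7e-03, 7.5e-04, 7.1e-04 and 7.2e-04). The ecdysone list also held 1 higher gene, and 14 were lower and 1 higher adjusted over the list alone. The list was set as a readout of developmental stage. The labels give no larval age beyond L3, so a difference in stage cannot be told apart from the genotype here.

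The detoxifying enzymes are glutathione S-transferases and cytochrome P450 enzymes, of whose genes 8 were lower in wing discs (18 higher and 8 lower adjusted over the list alone). GstD3 rose from 0.134 ± 0.0723 to 36.7 ± 2.55 CPM (SD, n = 3 each), a log2 fold change of 8.07 ± 0.27 (SE, adjusted p = 1.3e-05). GstE1 rose by 4.43 ± 0.22 on the log2 scale (SE, adjusted p = 9.5e-05), and GstT3 rose from 2.11 ± 0.305 to 34.0 ± 2.56 CPM (SD, n = 3 each; adjusted p = 2.3e-05). The P450 gene Cyp6a17 held 353 counts over the FtICD libraries and 0 over the wild type, at least 110-fold higher against a floor of 3 counts over the group. Other large changes were in Ect3, of a beta-galactosidase, at 8.01 ± 0.45, and ea, of the serine protease Easter, at 5.25 ± 0.18 (log2 fold change ± SE, adjusted p = 1.5e-04 and 1.4e-05). In the ft null, also set against w1118, GstD3, GstE1, GstT3 and ea were higher too (log2 fold change 3.28, 4.01, 1.75 and 4.34). Cyp6a17 held 2723 counts there against 2 in wild type. For these genes a difference of the stocks cannot be told apart from an effect of FtICD. The potassium channel gene SK was at -4.77 ± 0.27 and the serpin gene Spn100A at -4.27 ± 0.49 (log2 fold change ± SE, adjusted p = 1.5e-04 and 2.3e-03).

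Of 26 wing patterning genes, 7 were lower and 1 higher in FtICD discs (8 and 1 adjusted over the list alone; camera, adjusted p = 0.035; adjusted p = 0.65 with an estimated correlation). This list call was lost without wild-type replicate 2 (adjusted p = 0.057). The signal gene hh fell from 65.8 ± 2.16 to 23.0 ± 4.61 CPM (SD, n = 3 each), a log2 fold change of -1.51 ± 0.15 (SE, adjusted p = 1.0e-03). The wing pouch transcription factor gene nub was at -1.56 ± 0.25 (log2 fold change ± SE, adjusted p = 7.6e-03). Among 13 glycolysis genes, Ldh at -1.63 ± 0.18 and Gapdh1 at -2.04 ± 0.41 were lower (log2 fold change ± SE, adjusted p = 2.1e-03 and 0.016). Adjusted over the list alone, 5 were lower (camera, adjusted p = 0.026; adjusted p = 0.65 with an estimated correlation). The glycolysis list call was lost without wild-type replicate 3 (adjusted p = 0.091), and Gapdh1's call without FtICD replicate 2 (0.076) or wild-type replicate 2 (0.054).

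Of 18 Yorkie targets in wing discs, chinmo, a gene that maintains undifferentiated states, rose by 2.31 ± 0.22 on the log2 scale (SE, adjusted p = 1.0e-03) and 3 were lower. Adjusted over the list alone, 2 were higher and 3 lower (median and mean log2 fold change -0.15 and -0.07; camera, adjusted p = 0.90). Diap1, of the inhibitor of apoptosis, whose exons overlap asRNA:CR45889, was at -0.57 ± 0.13 (log2 fold change ± SE, adjusted p = 0.024); without any 1 of the 5 libraries other than FtICD replicate 1 its adjusted p lay between 0.053 and 0.093. Of 23 Hippo pathway genes, 3 were lower and none higher (4 lower and 1 higher adjusted over the list alone; camera, adjusted p = 0.17). The lower genes included yki itself, at -3.03 ± 0.49 (log2 fold change ± SE, adjusted p = 7.7e-03), with 100, 89.4 and 27.6 CPM in wild type. Although outside the low-recovery set, yki varied in the eye-brain libraries of the same table, at 8.09 and 4.49 CPM in wild type and 73.1, 25.3 and 70.4 CPM with FtICD. The cell death gene rpr rose by 0.85 ± 0.12 on the log2 scale (SE, adjusted p = 5.2e-03). Of 17 genes of damage and cell death, 1 was higher and 1 lower, also when adjusted over the list alone (camera, adjusted p = 0.63).

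In wing discs 1661 of 9416 genes passed the quasi-likelihood test, 722 higher and 939 lower, of which 341 and 594 changed at least 2-fold. The count was 872 without FtICD replicate 2, 1027 without wild-type replicate 1 and 885 without wild-type replicate 2. Of 371 low-recovery genes tested, 119 were lower and 14 higher, with a median log2 fold change of -0.80, and 1488 genes passed when this set was left out, an alternative chosen after the data were seen. Of 9 marker genes of the fat body, 2 were higher and none lower (5 higher adjusted over the list alone; camera, adjusted p = 0.072), with a median log2 fold change of 2.999. DESeq2 called 6 of them higher, limma-voom none, and 7 were higher by edgeR at an unadjusted p under 0.05. Of 8 marker genes of the salivary gland, 1 was lower and none higher (4 lower adjusted over the list alone; camera, adjusted p = 0.053), with a median of -2.15. DESeq2 called 4 of them lower and limma-voom 6, and 4 were lower by edgeR at an unadjusted p under 0.05. With a replicate block both lists passed camera (adjusted p = 8.7e-04 each). Carry-over of fat body or salivary gland was not tested in wing discs.

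In eye-brain complexes with FtICD (n = 3 against 2) Syngr rose from 4.94 ± 0.149 (SD, n = 2) to 60.9 ± 2.62 CPM (SD, n = 3), a log2 fold change of 3.62 ± 0.11 (SE, adjusted p = 8.2e-04). The glutathione S-transferase gene GstE1 rose by 3.09 ± 0.14 on the log2 scale (SE, adjusted p = 3.5e-03). The calls of ft, Syngr and GstE1 held when any 1 of the 5 libraries was left out. ChAT, of acetylcholine synthesis, whose exons overlap VAChT, rose by 1.30 ± 0.10 and Gad1, of GABA synthesis, by 0.52 ± 0.09 (SE, adjusted p = 0.010 and 0.048). They were the 2 of 16 neuronal genes that passed over all genes, with 3 higher adjusted over the list alone. The list's median was -0.15, its mean 0.01 and its camera adjusted p 0.85. Of 13 neuroblast genes, grh, whose exons overlap lncRNA:CR45270, was at -1.01 ± 0.10 and klu at -0.67 ± 0.10 (log2 fold change ± SE, adjusted p = 0.017 and 0.037). Adjusted over the list alone, 2 neuroblast genes were higher and 3 lower (camera, adjusted p = 0.44). Without wild-type replicate 2 the adjusted p of these 4 genes was 0.14 for ChAT, 0.32 for Gad1, 0.15 for grh and 0.23 for klu, and without FtICD replicate 1 it was 0.081, 0.20, 0.11 and 0.15. Without wild-type replicate 1 it was 0.064, 0.19, 0.085 and 0.12, and without FtICD replicate 2 the adjusted p of Gad1 was 0.11 and that of klu 0.067. Gad1 also did not pass without the filter (0.063), with a length correction (0.057) or in a joint fit (0.16).

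No Yorkie target among 19 passed in eye-brain complexes with FtICD, over all genes or adjusted over the list alone (median and mean log2 fold change -0.18 and 0.06; camera, adjusted p = 0.18). At an unadjusted p under 0.05 edgeR gave 5 of them as lower and none as higher, and DESeq2 called 3 lower, while limma-voom called none. The self-test with simulated counts recovered 10.4% of 2-fold changes in this comparison. Of 13 glycolysis genes, 2 were higher, and 8 adjusted over the list alone (camera, adjusted p = 2.7e-03; adjusted p = 0.93 with an estimated correlation). These were Gapdh1 at 2.03 ± 0.36 and Tpi at 1.73 ± 0.31 (log2 fold change ± SE, adjusted p = 0.047 and 0.049). Their calls were lost without FtICD replicate 1 (adjusted p = 0.17 and 0.17), FtICD replicate 2 (0.065 and 0.065) or wild-type replicate 2 (0.12 and 0.15), and that of Tpi with RLE size factors (0.051). The 13 mitochondrially encoded genes had a median log2 fold change of -0.86, and none passed on its own or adjusted over the list alone (camera, adjusted p = 1.6e-03; adjusted p = 0.93 with an estimated correlation). Of these, 2 were lower by edgeR at an unadjusted p under 0.05 and none by DESeq2. FtICD replicate 3 carries part of this shift, its list median lying 1.70 below FtICD replicates 1 and 2 (log2). Mitochondrial genes took 0.527% of counts there, 1.33 and 1.41% in those replicates and 1.89 and 1.78% in wild type. Without replicate 3 the list median was -0.49 (camera, adjusted p = 1.1e-03). The 20 Notch pathway genes had a median of -0.23, and none passed in either way (camera, adjusted p = 0.017; adjusted p = 0.93 with an estimated correlation). This list call was lost without FtICD replicate 1 (adjusted p = 0.051), FtICD replicate 3 (0.065) or wild-type replicate 1 (0.12), and with a replicate block (0.068). By edgeR at an unadjusted p under 0.05, 4 Notch genes were lower, and by DESeq2 3.

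In eye-brain FtICD replicate 3 genes of other tissues stood at levels not seen in the remaining libraries. The salivary glue gene Sgs3 was at 5013 CPM there and at 1.41 to 11.5 CPM in the other 4 libraries, and the larval serum protein gene Lsp2, of the fat body, was at 1864 CPM against 2.34 to 29.9. The salivary gland list lay a median log2 of 9.72 above FtICD replicates 1 and 2, the fat body list 7.38, the muscle list 1.43 and the haemocyte list 1.34, whereas the mitochondrially encoded list lay 1.70 below them. No gene of these 4 lists passed over all genes, and 1 haemocyte gene was higher adjusted over the list alone (camera, adjusted p = 0.44, 0.56, 0.44 and 0.11). With a replicate block the salivary gland list passed (adjusted p = 2.6e-09). Wild type has no replicate 3, so the blocked contrast rests on replicates 1 and 2 and does not bear on replicate 3. Without replicate 3 the salivary gland list had a median log2 fold change of -1.95. By edgeR at an unadjusted p under 0.05, 3 haemocyte genes and 1 muscle gene were higher, the same counts as with DESeq2. In all, 458 of 10841 genes passed in this comparison, 341 higher and 117 lower, of which 279 and 81 changed at least 2-fold. The count was 1837 with DESeq2 (1178 higher, 659 lower), 1725 in a joint fit of the FtICD tissues (1055 and 670) and 1280 with a replicate block (824 and 456). Without replicate 3 the count was 865, and 455 of the 458 genes were among them in the same direction. It was 10 without FtICD replicate 1, 55 without wild-type replicate 1 and 8 without wild-type replicate 2, where the lone wild-type library is assumed to vary as the FtICD libraries do.

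In ft null eye-brain complexes (n = 3 against 3), 11 of 17 Yorkie targets and 11 of 13 haemocyte genes were higher, and 14 of 20 eye genes and 12 of 16 neuronal genes were lower (camera, adjusted p = 1.1e-06, 1.1e-06, 7.9e-06 and 7.3e-05). With an estimated correlation the adjusted p was 0.29, 0.29, 0.16 and 0.39. The Yorkie target and Hippo regulator ex (FBgn0004583, 2L, 431227 to 448701), whose exons overlap crq, rose from 180 ± 20.8 to 614 ± 27.3 CPM (SD, n = 3 each), a log2 fold change of 1.77 ± 0.09 (SE, adjusted p = 2.8e-05). Its partner kibra (FBgn0262127, 3R, 14697689 to 14724261) rose from 35.5 ± 0.458 to 92.8 ± 4.36 CPM (SD, n = 3 each), a log2 fold change of 1.39 ± 0.06 (SE, adjusted p = 1.0e-05). The polarity gene crb was at 0.82 ± 0.07, the Notch ligand gene Ser at 0.68 ± 0.07 and fj, of the Golgi kinase that modifies Fat, at 0.62 ± 0.07 (log2 fold change ± SE, adjusted p = 1.5e-04, 2.9e-04 and 5.1e-04). No Yorkie target was lower, also when adjusted over the list alone, by edgeR at an unadjusted p under 0.05, or by DESeq2.

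Of 23 Hippo pathway genes, which share ex, kibra, crb and Mer with the Yorkie targets, 12 were higher and 2 lower in the ft null (12 and 3 adjusted over the list alone; camera, adjusted p = 9.9e-03; adjusted p = 0.29 with an estimated correlation). Schip1, of a kinase regulator, was lower at -1.23 ± 0.10 (log2 fold change ± SE, adjusted p = 1.6e-04). Of 16 Fat and Dachsous genes, ft among them, 6 were higher and 2 lower (7 and 2 adjusted over the list alone; camera, adjusted p = 0.024; adjusted p = 0.50 with an estimated correlation). The list call was lost without wild-type replicate 2 (adjusted p = 0.058). The myosin gene dachs (d), which acts downstream of Fat, rose from 167 ± 3.91 to 320 ± 17.7 CPM (SD, n = 3 each), a log2 fold change of 0.94 ± 0.06 (SE, adjusted p = 5.0e-05).

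Of 20 genes of eye specification and photoreceptors tested in the ft null, 14 were lower and 3 higher (15 and 3 adjusted over the list alone; camera, adjusted p = 7.9e-06; adjusted p = 0.16 with an estimated correlation). The photoreceptor transcription factor gene gl (FBgn0004618, 3R, 18367927 to 18372738) fell from 91.3 ± 2.39 to 29.9 ± 3.32 CPM (SD, n = 3 each), a log2 fold change of -1.61 ± 0.08 (SE, adjusted p = 2.8e-05). The receptor gene sev, whose exons overlap asRNA:CR44358, was at -0.84 ± 0.05 and the early regulator dac, a low-recovery gene, at -0.56 ± 0.05 (log2 fold change ± SE, adjusted p = 5.5e-05 and 2.9e-04). The early regulator Optix was higher, at 0.93 ± 0.07 (log2 fold change ± SE, adjusted p = 1.2e-04). Neuronal genes were lower in 12 of 16 cases and higher in none, also when adjusted over the list alone (camera, adjusted p = 7.3e-05; adjusted p = 0.39 with an estimated correlation). The RNA-binding protein genes fne and elav, the latter with exons overlapping arg, were at -1.01 ± 0.13 and -0.58 ± 0.05 (log2 fold change ± SE, adjusted p = 8.3e-04 and 1.6e-04). The gene cpx, of the synaptic protein complexin, was at -0.58 ± 0.07 (log2 fold change ± SE, adjusted p = 6.7e-04).

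All 13 haemocyte genes changed in the ft null, 11 higher and 2 lower, also when adjusted over the list alone (camera, adjusted p = 1.1e-06; adjusted p = 0.29 with an estimated correlation). Hml, of the clotting protein hemolectin, rose from 23.6 ± 5.56 to 174 ± 27.7 CPM (SD, n = 3 each), a log2 fold change of 2.88 ± 0.18 (SE, adjusted p = 5.0e-05). The scavenger receptor gene Sr-CI rose by 2.38 ± 0.15 on the log2 scale (SE, adjusted p = 5.0e-05). Salivary gland genes were lower in 7 of 9 cases and higher in none, also when adjusted over the list alone (camera, adjusted p = 2.0e-03; adjusted p = 0.39 with an estimated correlation). The glue gene Sgs1 was at 0.185 ± 0.109 against 4.76 ± 3.42 CPM (SD, n = 3 each; log2 fold change -4.68 ± 0.71, SE, adjusted p = 1.7e-03). Carry-over of other tissues at dissection was not tested in this set. For salivary gland and haemocyte genes, differing amounts of attached tissue cannot be told apart from the genotype. Ecdysone genes were lower in 11 and higher in 4 of 27 cases (12 and 4 adjusted over the list alone; camera, adjusted p = 0.013; adjusted p = 0.83 with an estimated correlation). ImpE2, an ecdysone-induced gene, was at -2.38 ± 0.31, and spok and nvd, of ecdysone synthesis, at -1.27 ± 0.16 and -1.54 ± 0.19 (log2 fold change ± SE, adjusted p = 8.4e-04, 8.7e-04 and 6.7e-04). As this list is a readout of stage and no larval age is labelled, a stage difference cannot be told apart from the genotype.

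Genes of glutathione S-transferases and cytochrome P450 enzymes were higher in 24 and lower in 9 of 72 cases in the ft null (24 and 10 adjusted over the list alone; camera, adjusted p = 0.010; adjusted p = 0.29 with an estimated correlation). Ribosomal protein genes were higher in 39 and lower in 7 of 85 cases (40 and 8 adjusted over the list alone). RpL3, whose exons overlap asRNA:CR31144 and snoRNA:Me18S-A425, was at 0.62 ± 0.07 and RpL41 at -0.74 ± 0.10 (log2 fold change ± SE, adjusted p = 4.4e-04 and 8.3e-04). With a length correction RpL41 did not pass (adjusted p = 0.053). This list passed camera (adjusted p = 0.020; adjusted p = 0.87 with an estimated correlation), a call lost without ft null replicate 1 (adjusted p = 0.071) or wild-type replicate 2 (0.051). Mitochondrially encoded genes were lower in 8 of 9 cases and higher in none, also when adjusted over the list alone (camera, adjusted p = 0.010; adjusted p = 0.84 with an estimated correlation). The complex I gene mt:ND5 was at -1.18 ± 0.26 (log2 fold change ± SE, adjusted p = 9.2e-03). Mitochondrial genes took 0.307 ± 0.145% of counts in the ft null and 0.8294 ± 0.284% in wild type (SD, n = 3 each). In all, 4440 of 9978 genes passed the quasi-likelihood test, 2346 higher and 2094 lower, of which 367 and 455 changed at least 2-fold.

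**Figure D3:**
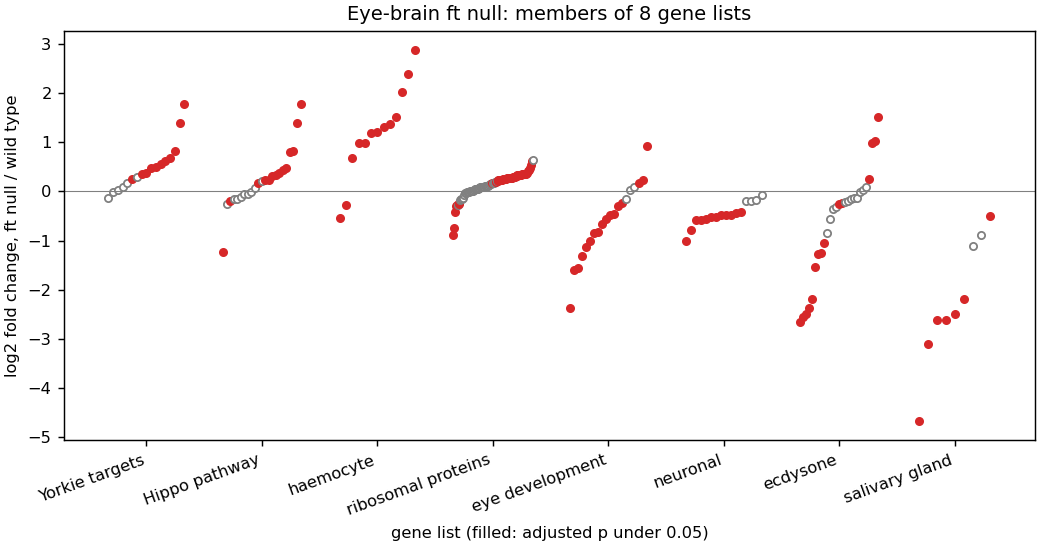
Log2 fold change, ft null against wild type in eye-brain complexes, for the tested members of 8 gene lists; each point is a gene, filled red where its adjusted p is under 0.05 and open otherwise. Of the Yorkie targets 11 of 17 are filled above 0 and of the neuronal genes 12 of 16 are filled below 0.

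Across the 3 FtICD tissues, 109 of 8771 genes tested in each were called in the same direction in all 3. Of these, 65 were higher and 44 lower, against a total of 8.3 expected of independent lists. A difference of the stocks from w1118 would recur in each tissue, and this expectation does not allow for it. By pairs, wing disc and eye-brain shared 270 called genes, 148 in the same direction (32.3 expected) and 122 in opposite directions (36.8 expected). Embryo and eye-brain shared 288, with 178 and 110 (117.9 and 116.2 expected), and embryo and wing disc 920, with 645 and 275 (419.6 and 415.4 expected). Higher in all 3 were ft, GstE1, ea, phr, of a DNA photolyase, and IntS12, of the Integrator complex. Lasp, the deacetylase gene Sirt2, the epithelial transcription factor gene grh and the low-recovery gene Osbp, whose exons overlap CG11771, were lower in all 3. The log2 fold changes of Lasp were -2.35 ± 0.07, -1.56 ± 0.10 and -2.02 ± 0.19 in embryo, wing disc and eye-brain, and those of grh -0.76 ± 0.09, -0.74 ± 0.12 and -1.01 ± 0.10 (SE). In the ft null both were higher, Lasp at 0.59 ± 0.08 and grh at 0.52 ± 0.05 (log2 fold change ± SE, adjusted p = 8.1e-04 and 3.0e-04). The eye-brain FtICD calls of these genes other than ft and GstE1 were each lost without wild-type replicate 2, with adjusted p between 0.073 and 0.15. All of these but Osbp were also lost without FtICD replicate 1 (0.073 to 0.11), and all but Osbp and phr without wild-type replicate 1 (0.055 to 0.085). Of the 109 genes, 100 were also tested in the ft null, where 36 of the higher ones were again higher, 21 of the lower ones again lower and 9 went the opposite way. Without eye-brain FtICD replicate 3, 155 genes were called in all 3 tissues. Without eye-brain FtICD replicate 1, 10 genes passed in eye-brain complexes, so no more than 10 could be called in all 3.

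Of 9871 genes tested in both eye-brain comparisons, 233 were called in both, more than expected of independent lists (Fisher's exact test, two-sided, odds ratio 1.47, p = 1.1e-04). They went the same way in 182 cases, against 99.2 expected, and opposite ways in 51, against 94.2 expected. A difference of the stocks from w1118 could be shared by both comparisons, which these expectations do not allow for. Compared with the ft null across tissues, embryo FtICD shared 2380 called genes, of which 911 went the same way (1146 expected) and 1469 opposite ways (1145 expected). Wing disc FtICD shared 849, of which 567 went the same way (333.7 expected) and 282 opposite ways (349.9 expected). Among the genes changed at least 8-fold in both eye-brain comparisons, 22 of 22 went the same way. The P450 gene Cyp6a17 held 994 counts over the FtICD libraries and 3 over their wild type, a ratio of 182 with a 95% interval of 62.0 to 882. In the ft null it held 2723 against 2 counts, a ratio of 1150 with an interval of 317 to 9460. The chaperone gene Hsc70-2 was at -5.86 ± 0.36 with FtICD and -8.71 ± 0.44 in the ft null (log2 fold change ± SE, adjusted p = 6.2e-03 and 2.6e-05). CG18853, chosen after its values were seen, held 3 counts with FtICD and 7096 in wild type, a ratio of 4320 with an interval of 1480 to 20900, and was at least 2140-fold lower in the ft null, where it held 0 counts. In the opposite direction, Syngr was higher with FtICD and lower in the ft null, at -0.42 ± 0.11 (log2 fold change ± SE, adjusted p = 0.015). That call was lost without ft null replicate 1 (adjusted p = 0.056) or wild-type replicate 1 (0.052) of that set. Without wild-type replicate 2 of the FtICD table the adjusted p of Cyp6a17 and Hsc70-2 was 0.075 each, and without FtICD replicate 1 it was 0.058 and 0.073. Without FtICD replicate 3, 462 genes were called in both comparisons, 341 in the same direction. Without FtICD replicate 1, 10 genes passed in the FtICD comparison, so no more than 10 could be called in both.

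**Figure D4:**
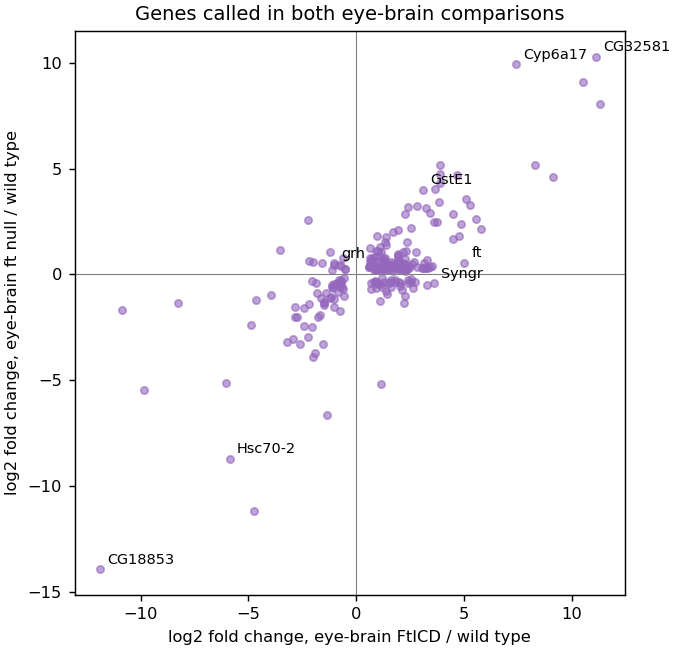
Log2 fold changes of the 233 genes called in both eye-brain comparisons, FtICD against wild type on the horizontal axis and ft null against wild type on the vertical axis; each point is a gene. Of the genes shown, 182 lie in the quadrants of equal sign and 51 in those of opposite sign.

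The effect of FtICD differed between wing disc and embryo for 3815 of 12088 genes by an interaction test, between eye-brain and embryo for 3826 of 12417 and between eye-brain and wing disc for 865 of 11440 (1579 with DESeq2). In these 3 tests the share of low-recovery genes that differed was 36.6, 46.3 and 26.9%, beside 31.4, 30.2 and 6.77% of other genes; the gaps between shares were not tested. The potassium channel gene SK was at -4.77 in wing discs and at 0.10 in embryos, and Pepck2 at 1.83 in wing discs and -2.47 in embryos (log2 fold change; adjusted p of each difference 1.3e-08). Map205 was at 0.40 in eye-brain complexes and 3.66 in embryos (log2 fold change; adjusted p of the difference 8.1e-06). The ft null and FtICD effects in eye-brain complexes differed for 1873 of 10916 genes, each against its own wild type (23.7% of low-recovery genes and 16.9% of others). Among these was Syngr, at -0.42 and 3.62 (log2 fold change in ft null and FtICD; adjusted p of the difference 4.6e-06). The cuticle protein gene Cpr66D rose 8.01-fold in the ft null and was at a log2 fold change of -0.34 with FtICD (adjusted p of the difference 9.5e-06). Without eye-brain FtICD replicate 3, the effects differed for 2493 genes. Every effect here is taken against w1118, so differences of the stocks can enter these tests.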

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

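The tests of a strain difference, of a response to Fat activity and of another library batch, with each library held out in turn, were chosen only after the result was seen, and the fits without ribosomal RNA genes and with a length correction were added after the data were seen.

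Genes called in both eye-brain comparisons mostly went the same way, in 78.1% of 233 cases, although FtICD adds a domain of Fat and the ft null removes Fat. Of those changed at least 8-fold in both, 100% went the same way (22 of 22; 95% exact interval 84.6 to 100) and 0% opposite ways. Across tissues, embryo FtICD and the ft null went the same way in 38.3% of 2380 genes called in both, and wing disc FtICD and the ft null in 66.8% of 849. The shares within eye-brain restate the pattern that prompted them, so they decide nothing about its source. A strain difference between the w1118 stock and the other genotypes and a response to changed Fat activity cannot be told apart here. Both comparisons use w1118 as control, and FtICD need not act opposite to the loss of ft.

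Eye-brain FtICD replicate 3 correlated with FtICD replicates 1 and 2 at 0.937 across genes, against 0.980 between those replicates; genes are not independent replicates. Lower depth is argued against, since 1 other library, wild-type replicate 2, had a lower total and correlated with its partner at 0.981. Carry-over of other tissues may account for part of it, with the salivary gland list a median log2 of 9.72 above the other FtICD libraries (Sgs3 at 5013 CPM, Lsp2 at 1864), though the eye-brain dissection as labelled names no step that would remove such tissue. Another library batch may account for another part, since 71.4% of the low-recovery genes were at least 2-fold higher in replicate 3. Those genes were chosen for low values in the other 4 libraries, which lifts a library left out of the choice. With the set chosen from 3 libraries and the fourth held out, the share was 3.97 to 8.54% for 3 of them and 42.0% for FtICD replicate 1, against 66.5 to 76.9% for replicate 3 on the same sets. Recovery thus also varied within the FtICD replicates, so a batch of replicate 3 alone is not shown. A trend with gene length stays open (Spearman's rho 0.27 across genes, between the bounds set for and against it).

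In embryos over 50% of the genes tested were called. Ribosomal RNA took more of the counts with FtICD, and without its genes 99.1% of the other called genes were still called in the same direction. TMM scaling already allows for counts taken by such genes, so this fit could hardly have come out otherwise. It does not decide whether differences of the libraries that go with the ribosomal share play a part. A trend with gene length is argued against as the whole cause, since 79.9% were still called in the same direction with a length correction. A difference in stage within the collection window could be part of it and cannot be told apart from the genotype, as the cuticle list had a median absolute log2 fold change of 0.52 against 0.37 for all genes, but 70.5% of its 61 called members went one way, under the 75% set as the bound. The effect of FtICD itself and that of the strain stay open as well.

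Chance in how the libraries were grouped is argued against as the source of the embryo count. Of 35 splits of the 8 libraries 1, the real one, gave 6000 genes and the highest other gave 1. The other splits mix the genotypes, which widens the spread within groups and lowers their counts. Any difference of handling or stock that goes with genotype would give the same result. For wing discs the real split gave 1661 genes and the highest other 0, and for the ft null the real split gave 4440 and the highest other 2, with 1 split as large in each; the 10 splits of each are too few for a share under 0.05.

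Of 92 groups of 4 values examined, 8 had a library far from the other 3, and chance flags about 1 in 20 groups. In FtICD embryos, lncRNA:roX1 was at 823.6 CPM in replicate 4, against 735 to 749 in the others. Hsp70Bb was at 795.7 CPM and Hsp22 at 276.7 CPM in replicate 1, against 93.9 to 175 and 21.7 to 56.7 in the others. Mitochondrial genes took 2.187% of counts in replicate 4, against 1.66 to 1.75%, and the low-recovery median there was -2.008, against -1.93 to -1.92. In wild-type embryos, ft was at 32.91 CPM and lncRNA:roX2 at 28.47 CPM in replicate 1, against 22.4 to 23.8 and 23.0 to 23.7 in the others. Hsp22 was at 9.528 CPM in wild-type replicate 3, against 3.25 to 3.83 in the others.

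The effect of FtICD, taken against w1118 and so including any difference of the stocks, differed between tissues by the interaction test. GstD3, GstT3 and Cyp6a17, listed here, were also higher in the ft null. For them a difference of the stocks cannot be told apart from an effect of FtICD. Between wing disc and embryo 3815 genes differed, with log2 differences of 4.416 for Pepck2, -4.734 for SK, 6.661 for Ect3, 4.849 for GstT3 and 8.872 for GstD3. Between eye-brain and embryo 3826 genes differed, with -3.268 for Map205, 2.592 for not, 6.737 for Cyp6a17 and -2.339 for 5-HT1A. Between eye-brain and wing disc 865 genes differed, with -7.637 for Ect3, 4.184 for SK, -3.14 for Ac3 and -1.944 for NaPi-III.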

How the results depend on the processing

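The fits without ribosomal RNA genes, with a length correction, without low-recovery genes, and without eye-brain FtICD replicate 3 for interactions and overlaps were chosen after the data were seen. Of 2541 alternatives for 181 named-gene results, 2419 kept direction and side of the threshold, 118 kept direction without passing, and 4 reversed. Of the 118, 99 came from leaving out 1 library, 73 of them in eye-brain FtICD. The sign of lncRNA:roX2, which had not passed, reversed without wild-type replicate 2 in eye-brain FtICD (log2 -1.39 to 0.11 over the libraries left out). In the ft null set it reversed to 0.19, 0.08 and 0.15 without ft null replicate 2, ft null replicate 3 and wild-type replicate 2 (log2 -0.42 to 0.19 over all 6).

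A minimum 2-fold change lowered the counts by its construction, to 1271 in embryos, 935 in wing discs, 822 in the ft null, 67 for all 3 FtICD tissues and 82 for both eye-brain comparisons. In eye-brain FtICD the count of 458 became 1837 with DESeq2, 1280 with a replicate block and 1725 in the joint fit, for which the cause was not tested. In this comparison the block takes FtICD replicate 3 out of the contrast, since wild type has replicates 1 and 2 only. With DESeq2, 1579 genes differed between eye-brain and wing disc effects, 221 were called in all 3 tissues and 940 in both eye-brain comparisons, and with a replicate block 564 in both; the cause was not tested. Replicate numbers did not pair libraries, correlations of equal numbers ranging from -0.208 to 0.231; blocked counts were 5791 in embryos, 1139 in wing discs and 3262 in the ft null. Without ribosomal RNA genes the counts were 6002, 1662, 463 and 4440, with a length correction 5615, 1823, 480 and 4368, and without low-recovery genes 1488 in wing discs and 425 in eye-brain FtICD.

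Leaving out 1 library gave 5407 to 6058 genes in embryos, 872 to 1561 in wing discs, 8 to 865 in eye-brain FtICD and 3097 to 5068 in the ft null. Without eye-brain FtICD replicate 3, effects differed for 4045 genes against embryo, 875 against wing disc and 2493 against the ft null, 155 genes were called in all 3 tissues and 462 in both eye-brain comparisons. Without eye-brain FtICD replicate 1, 10 genes passed in eye-brain FtICD, so neither overlap could exceed 10. Fewer samples are part of the construction of these fits, and the cause of rises was not tested. With an estimated correlation 0 lists passed in each of the 4 comparisons. With a replicate block 7 lists passed in wing discs; the cause was not tested. With a replicate block 7 lists passed that had not: heat shock in embryos (adjusted p = 2.0e-03), complexes II to V, fat body and salivary gland in wing discs (0.020, 8.7e-04 and 8.7e-04), wing patterning and salivary gland in eye-brain FtICD (0.027 and 2.6e-09), and muscle in the ft null (0.048). Notch in eye-brain FtICD was lost (0.068). The salivary gland list of eye-brain FtICD had a median log2 fold change of 6.34 with all libraries and -1.95 without FtICD replicate 3. The block takes that replicate out of the contrast, so the blocked call of this list need not be a rise. The test with fry asks another question, whether the genes of a list move on balance one way, whatever other genes do. By it 14 lists passed in embryos and 0 in eye-brain FtICD. Lists that passed camera but not fry were glycolysis and wing patterning in wing discs (adjusted p = 0.056 and 0.074), the 3 of eye-brain FtICD (0.24 to 0.57) and ribosomal, ecdysone and mitochondrially encoded genes in the ft null (0.069 to 0.083). Leaving out 1 library gave 7 to 8 lists in embryos, 3 to 9 in wing discs, 2 to 4 in eye-brain FtICD and 10 to 12 in the ft null. Depth limits genes with few counts, given as bounds or intervals.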

Other observations

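The test of a link to chromosome arm 2L was set before its result was seen.

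Further genes changed in ft null eye-brain complexes in lists that did not pass as a whole. Of 20 Notch pathway genes 6 were higher and 9 lower (6 and 10 adjusted over the list alone; camera, adjusted p = 0.61). The gene fng, of the glycosyltransferase Fringe, was at 0.70 ± 0.05 and E(spl)mdelta-HLH, a Notch-induced repressor gene, at -1.54 ± 0.16 (log2 fold change ± SE, n = 3 each, adjusted p = 6.7e-05 and 3.3e-04). Of 26 wing patterning genes 7 were higher and 6 lower (7 and 7 adjusted over the list alone; camera, adjusted p = 0.79). The T-box gene Doc1 was at 1.54 ± 0.11 (log2 fold change ± SE, adjusted p = 6.7e-05). Of 42 cuticle genes 13 were higher and 13 lower, also when adjusted over the list alone (camera, adjusted p = 0.25). Cpr66D rose from 11.6 ± 1.40 to 92.5 ± 1.83 CPM (SD, n = 3 each), and verm, of a chitin deacetylase, was at 0.96 ± 0.06 (log2 fold change ± SE, adjusted p = 5.2e-05). Of 28 cell cycle genes 13 were higher and 3 lower (15 and 4 adjusted over the list alone; camera, adjusted p = 0.084).

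In FtICD embryos 13 haemocyte genes went both ways, 6 higher and 3 lower (6 and 4 adjusted over the list alone; camera, adjusted p = 0.93). Hml was at 1.92 ± 0.23 and PPO2, of the prophenoloxidase of crystal cells, at -1.86 ± 0.18 (log2 fold change ± SE, n = 4 each, adjusted p = 5.8e-05 and 1.5e-05). Of 17 muscle genes 4 were higher and 4 lower, also when adjusted over the list alone (camera, adjusted p = 0.64). The actin gene Act87E, whose exons overlap lncRNA:CR45591, was at -1.08 ± 0.08 (log2 fold change ± SE, adjusted p = 3.7e-06).

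A hypothesis for the large changes in the ft null is that genes on 2L, the arm that carries the ft alleles, may differ through linked variants. Of 254 called genes changed at least 4-fold, 55 lay on 2L (21.7%), against 753 of 4146 other called genes (18.2%), an odds ratio of 1.25 with a 95% interval of 0.897 to 1.71 (Fisher's exact test, two-sided, p = 0.18). The interval holds both 1 and values above 1.5, so the hypothesis was neither borne out nor excluded.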
